A study of Mus musculus with 8 samples.

How the data were processed

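RNA of sorted hepatic stellate cells from 8 samples, 4 control and 4 knockout, was measured on 1 array each. Per the labels' protocols, the mice had a C57BL/6J background and received poly(I:C) 3 times, and stellate cells were taken from the liver 2 weeks later by density centrifugation and sorting on retinoid autofluorescence and lysed right after the sort. RNA was purified on columns and 150 ng per sample went into cDNA synthesis and terminal labelling, per the labels' protocols. The values are deposited log2 expression values, 1 per probe set and array, and per the labels' protocols and the submitters' processing notes they were normalized with the Robust Multichip Algorithm (RMA). RMA corrects background, brings the arrays to a common distribution and summarises the probes of a probe set, and it compresses differences of dim and of very bright probe sets. The version of RMA, the annotation used with it, scan dates and batches are not given in the sources used here, so no batch was tested. No detection calls were used, and the levels of 1194 olfactory and vomeronasal receptor genes, which stellate cells are not known to use, served as a guide to unexpressed levels (median 5.40, 95th percentile 6.77).

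The table held 35556 probe sets. A platform annotation that pairs probe sets with genes listed 23410 of them, 21789 with 1 gene symbol and 1621 with several, and 12146 were unnamed here. Symbols were looked up by gene identifier in a RefSeq gene table (assembly GRCm38.p6) for 21698 probe sets, which changed 0 symbols. Probe sets with several genes were left out. For the 999 genes with more than 1 probe set, the probe set with the highest mean over the 8 arrays stood for the gene, which gave 19938 genes. Coordinates are not given, because no genome build is named for the values.

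Groups and replicate numbers came from the sample titles. The main comparison, knockout minus control over all 8 arrays with no covariate, was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. No filter on dim genes and no fold threshold was set. For Lhx2 and for marker scores, exact two-sided permutation tests ran over all 70 assignments of 4 and 4 arrays. The design, the alternatives, the lists and the rule for named genes were fixed before the data were examined.

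The 20 gene lists and 12 lists of cell type markers held 648 entries, of which 600 were measured. Each was tested with camera at a preset correlation of 0.01, with adjustment over the 32 lists, and with an estimated correlation and fry as alternatives. Counts of members past the threshold are given over all genes tested and adjusted over the list alone. Named genes were Lhx2, the 15 largest rises and 15 largest falls among genes past the threshold with non-overlapping groups, up to 4 members of each list with called members first, and Acta2, Col1a1, Col1a2, Timp1, Lox, Hgf, Lrat, Reln, Des, Alb and Ptprc whatever their value. Predicted genes, receptor and immunoglobulin segments were counted but not named by size. The rule gave 156 genes, and 50 more were named after their values were seen.

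The alternatives were median centring and quantile normalization of the deposited values, 2 filters on dim genes, eBayes with a trend and robust fitting, array weights, the mean of the probe sets of a gene, every annotated probe set on its own, leaving out each array in turn, a 1.5-fold threshold and a threshold of 0.01. A further 2 alternatives were added after the data were seen, namely hepatocyte and endothelial marker scores (14 and 12 genes) as covariates, and the fit without control 1 and control 4. Bootstrap intervals of medians over genes used 10000 draws at a confidence level of 95%, and cover the choice of genes, not the arrays.

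The limma step was tested on simulated data with the real means and spreads of the 19938 genes of the comparison of knockout against control. Of 50 genes changed by 0.5 on the log2 scale 88% were recovered, and of 50 each changed by 1, 2 and 3, 100%, with 6 false calls (3% of calls). Camera recovered all 10 simulated lists of 20 genes shifted by 0.5 and called 0 of 30 unshifted lists, with the preset and with the estimated correlation. Correlation between genes is not among the stated settings of the simulation. In the real data it was estimated at 0.77 for the immediate-early list and 0.91 for the sinusoidal endothelial list. The 0 of 30 therefore does not give the rate of false calls for such lists.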

Results

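Gene expression was measured on Affymetrix Mouse Gene ST arrays in hepatic stellate cells, the retinoid-storing pericytes of the liver sinusoid, sorted from mouse liver by the autofluorescence of their retinoids. The control group held 4 arrays from mice with floxed Lhx2 and no Cre, replicates 1 to 4, and the knockout group held 4 arrays from mice with floxed Lhx2 and the Mx1Cre transgene, replicates 5 to 8. Mx1Cre is switched on by interferon in many cell types of liver and blood, and both groups had received 3 doses of poly(I:C), a double-stranded RNA that induces interferon, 2 weeks before the cells were isolated. Only the knockout group carried Cre, so loss of Lhx2 and effects of the transgene cannot be told apart. Loss of Lhx2 in the stellate cells and in other cells cannot be told apart either. The series title names stellate cell activation, the change of these cells towards matrix-producing myofibroblasts, as the question. The deposited log2 expression values ran from 4.19 to 14.4, and the array medians lay between 7.42 and 7.47. Pearson correlations across probe sets were 0.987 to 0.996 within the control group, 0.993 to 0.996 within the knockout group and 0.984 to 0.991 between groups. The labels do not say whether each array came from a separate animal, so the p-values measure the spread between these arrays, which may be technical. The number of arrays limits the precision.

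Lhx2, a LIM homeobox transcription factor and the deleted gene, was lower in each of the 4 knockout arrays than in each control array. Its mean log2 level was 11.95 ± 0.08 (SD, n = 4) in the control group and 11.29 ± 0.17 (SD, n = 4) in the knockout group, which left 63.3% of the control level. The difference of -0.66 had a standard error of 0.09 (limma adjusted p = 0.00136). An exact two-sided permutation test gave p = 0.0286, the smallest value that 4 arrays against 4 allow. The gene had 1 probe set, and the labels do not give the floxed part, so some or all of its probes may lie outside the deleted sequence and the level then does not measure the deletion.

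**Figure D1:**
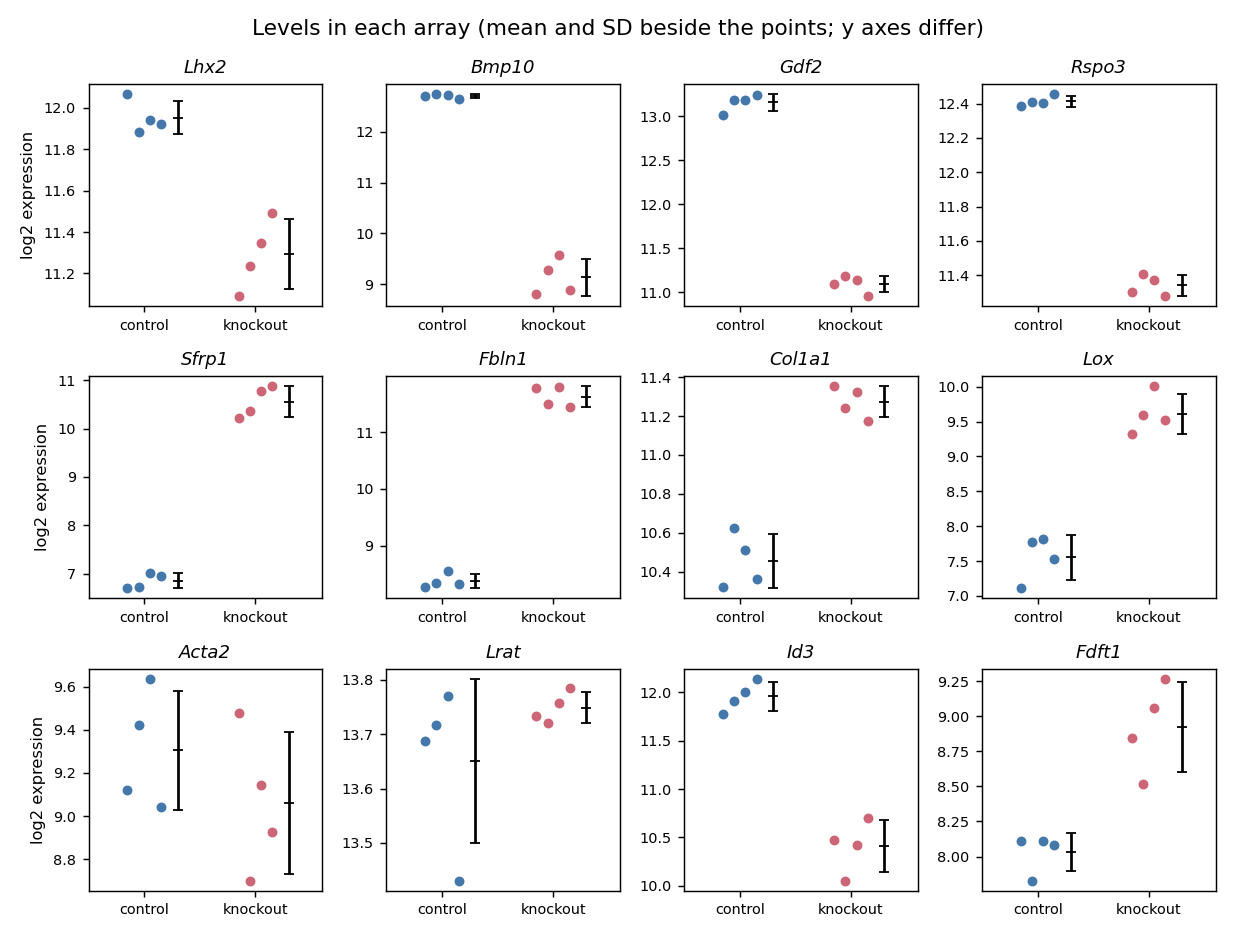
Log2 expression of 12 genes in each of the 8 arrays (points), with the group mean and SD beside the points, and a separate y axis for each gene. Lhx2, Bmp10, Gdf2, Rspo3 and Id3 lay lower in all 4 knockout arrays, Sfrp1, Fbln1, Col1a1, Lox and Fdft1 lay higher in all 4, and the groups overlapped for Acta2 and Lrat.

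The sorted cells of the knockout had higher mRNA levels of many secreted matrix genes, and lower levels of Bmp10 and Gdf2, while BMP ligands as a whole went both ways. Some markers of portal fibroblasts, such as Cd34 and Dpep1, rose along with the matrix genes. Svep1, a large matrix adhesion protein, rose 17.6-fold from a log2 level of 7.62 ± 0.09 to 11.76 ± 0.17 (SD, n = 4 each), and Adamtsl1, a matrix protein of the ADAMTS-like family, rose 17.4-fold. Bmp10, a circulating ligand of the BMP family, fell from 12.71 ± 0.05 to 9.13 ± 0.36 (SD, n = 4 each), a log2 difference of -3.58. Gdf2, which encodes BMP9, fell by 2.06 on the log2 scale from 13.15 ± 0.10 (SD, n = 4). Bmp5 fell by 0.36 (SE 0.05) and Bmp4 rose by 0.69 (SE 0.08), both chosen after their values were seen. Of 19938 genes tested, 749 were higher and 723 lower in the knockout at an adjusted p under 0.05 in limma, and 3484 had an unadjusted p under 0.05. Of the 1472 genes past the adjusted threshold, 523 changed at least 1.5-fold (284 higher, 239 lower) and 204 at least 2-fold (121 higher, 83 lower). The 4 arrays of one group all lay on one side of the other group for 1453 of the 1472 genes, and for 2533 of all genes tested, where chance separates 2.86%. Without control 1 and control 4, the control arrays with the highest hepatocyte and endothelial marker levels, 776 genes changed (371 higher, 405 lower), in a comparison of fewer arrays that was added after the data were seen.

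The 15 largest rises went on with Lgi2, a secreted leucine-rich repeat protein (log2 change 3.84, SE 0.12), Sfrp1, a secreted Wnt antagonist (3.71, SE 0.15), Fbln1, a fibulin of the matrix (3.25, SE 0.10), and C7, a component of the terminal complement complex (3.20, SE 0.15). Cd34, a sialomucin of progenitor, endothelial and fibroblast surfaces, rose by 3.08 (SE 0.23), Gas6, a ligand of the TAM receptor kinases, by 3.01 (SE 0.27), and Htra1, a secreted serine protease, by 2.92 (SE 0.09). The remaining rises were of Rpp25, Pi15, Pcsk6, Clmp, Dpep1 and Tmem119, with log2 changes of 2.85, 2.68, 2.52, 2.39, 2.37 and 2.36. The largest fall was that of Disp2, a Dispatched-like membrane protein, at -3.64 (SE 0.07), and Egfem1 followed Bmp10 at -2.91 (SE 0.05). Other falls were of Epor, the erythropoietin receptor (-2.24, SE 0.14), Nr1h5, a nuclear receptor related to the bile acid receptor (-2.15, SE 0.15), Lipg, endothelial lipase (-2.10, SE 0.16) and Grhl3, a transcription factor (-2.01, SE 0.08). Acvr1c, the activin receptor ALK7, fell from 8.01 to 6.17, a level under the 95th percentile of 6.77 of 1194 olfactory and vomeronasal receptor genes, so the size and the rank of its fall are uncertain. The control levels of Sfrp1 (6.85) and Pi15 (6.87) and the knockout levels of Adgre4 (6.85) and Galnt14 (6.86) lay close to that percentile, so the sizes and ranks of these changes are uncertain too. Dcdc2a, Adgre4, Galnt14, Igsf21 and Lratd1 also fell, with log2 changes of -2.47, -2.25, -2.20, -1.99 and -1.88. Raet1d fell by 2.66, but it belongs to a family of near-identical genes and its level is uncertain. The rule that named these 30 genes required non-overlapping groups and an adjusted p under 0.05. Their adjusted p in limma lay between 1.02e-08 and 0.000216.

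Of the 32 fixed gene lists, 14 passed limma's camera test with its preset correlation, 6 with higher and 8 with lower levels. With an estimated correlation 0 of the 32 passed camera, where 8 had an unadjusted p under 0.05. Fry passed 14 lists, 10 of them shared with camera. It tests whether the average change of a list, scaled by the spread of each gene, differs from 0. A list with members changed in both directions can therefore pass it. Fry alone passed the growth factor, retinoid, YAP, and erythroid and platelet lists, and camera alone the immediate-early, unfolded protein response, cell cycle and sinusoidal endothelial lists. Genes named below to complete a count of 5 or fewer, outside the naming rule, were chosen after their values were seen; these were Adamtsl2, Wnt4, Kitl, Cxcl12, Vim, Postn, Mmp14, Timp2, Inhba, Tgfbr1, Pmepa1, Ccn4, Fzd1, Notch1, Notch2, Notch3, Smo, Ifit2, Mfap4 and Smtn.

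Matrix genes rose, as did 5 of 14 portal fibroblast markers, of which Dpt, Eln and Mfap4 are also matrix genes. Of 29 measured matrix glycoproteins, proteoglycans and crosslinkers, 17 rose, 1 fell and 11 did not pass (adjusted over the list alone, 19 rose and 1 fell). Besides Fbln1, the risen members included Dpt, dermatopontin (log2 change 2.28, SE 0.34), Ogn, osteoglycin (2.14, SE 0.17), and Lox, the collagen and elastin crosslinking enzyme (2.05, SE 0.18), and the member that fell was Efemp1, fibulin-3 (-0.74, SE 0.06). The list passed camera (adjusted p = 2.62e-14; adjusted p = 0.0836 with an estimated correlation). Of 18 collagens, 6 rose and 12 did not pass (adjusted over the list alone, 8 rose and 1 fell). The 6 were the type VI chains Col6a2 (1.42, SE 0.08), Col6a3 (1.10, SE 0.08) and Col6a1 (1.01, SE 0.08) and the fibrillar chains Col3a1 (0.97, SE 0.06), Col1a1 (0.82, SE 0.08) and Col1a2 (0.59, SE 0.06). The collagens passed camera as well (adjusted p = 8.92e-07; adjusted p = 0.0836 with an estimated correlation). Matrix proteases and inhibitors had 5 risen and 1 fallen of 16 members (adjusted over the list alone, 6 and 1): the metalloproteases Mmp23 (1.12), Mmp2 (1.05) and Mmp14 (0.28), the plasminogen activator Plat (1.07) and the inhibitor Timp2 (0.21) rose, and the inhibitor Timp3 fell by 0.67. That list passed camera (adjusted p = 0.00293; adjusted p = 0.138 with an estimated correlation). Timp1 had a change of 0.33 (SE 0.16, adjusted p = 0.346). Each of 5 arrays, control 1, control 2, control 4, knockout 6 and knockout 7, when left out, took the risen proteases from 5 to 3: Mmp14 then reached an adjusted p of up to 0.0992 (lost also without control 3 or knockout 8) and Timp2 of up to 0.0811 (lost also without knockout 8).

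The contractile markers of myofibroblasts did not move together. Of 26 measured myofibroblast contractile and activation genes, 8 rose, 2 fell and 16 did not pass (adjusted over the list alone, 8 rose and 3 fell). The largest rises were of matrix proteins and matrix enzymes, Tnc, tenascin C (2.22, SE 0.15), Lox, its relative Loxl1 (1.33, SE 0.10) and Mmp2. Tagln, an actin-binding protein of smooth muscle, rose by 0.77 (SE 0.13). Acta2, smooth muscle actin, had log2 levels of 9.30 ± 0.28 in the control and 9.06 ± 0.33 in the knockout group (SD, n = 4 each; limma adjusted p = 0.61). Postn, periostin, fell by 0.44 and Vim, vimentin, by 0.19. The list median was -0.002 and its mean 0.32, so median and mean differed in sign; camera gave a rise (adjusted p = 0.00458; adjusted p = 0.286 with an estimated correlation). The call of Vim was lost when any array except knockout 7 was left out, with an adjusted p of up to 0.141. Vascular smooth muscle and pericyte markers had 1 risen (Tagln) and 4 fallen members of 14 (adjusted over the list alone, 1 and 6). The fallen members were Rgs4, a regulator of G protein signalling (-1.60, SE 0.15), Mcam, an adhesion molecule (-1.09, SE 0.08), Kcnj8, a potassium channel of pericytes (-0.39, SE 0.07), and Smtn, smoothelin (-0.36, SE 0.05). Camera gave an adjusted p of 0.0072 for that list (adjusted p = 0.175 with an estimated correlation).

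**Figure D2:**
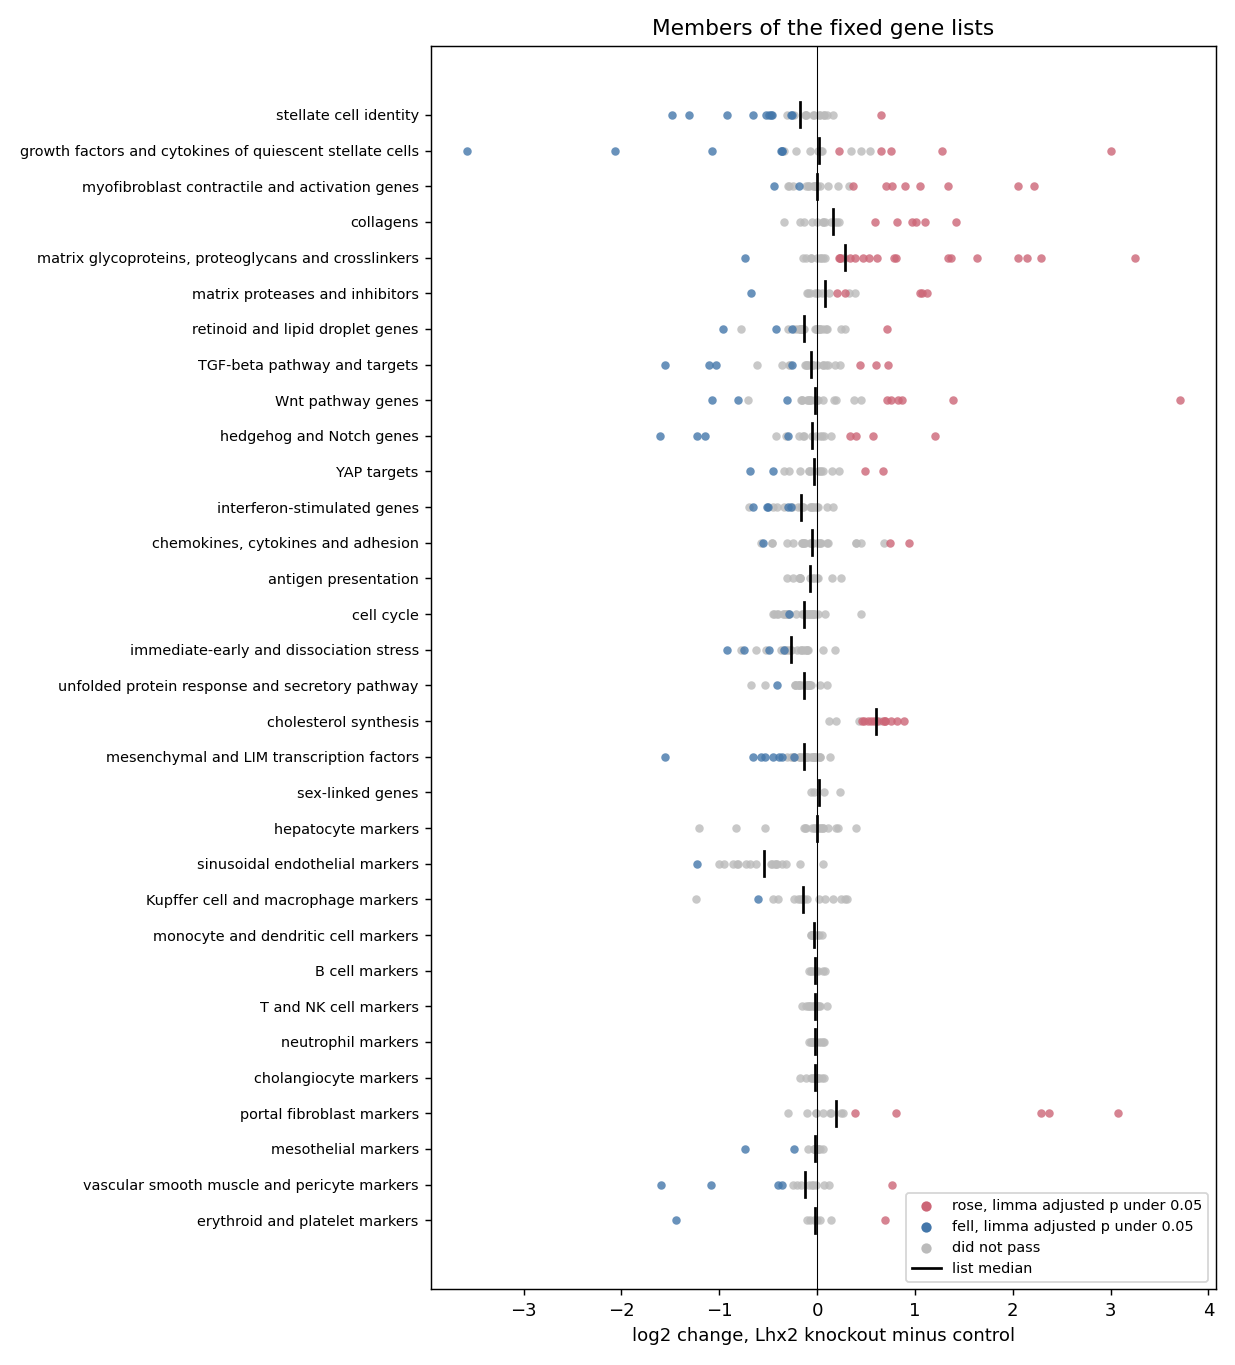
Log2 change of each measured member of the 32 fixed lists (x axis, knockout minus control; 1 point per gene), coloured by whether it rose, fell or did not pass in limma, with a black bar at each list's median. Of 16 cholesterol synthesis genes 12 rose and their median was 0.60, while the members of the B cell, T and NK cell, neutrophil and cholangiocyte lists lay close to 0.

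Genes that mark stellate cells fell in part. Of 24 measured stellate cell identity genes, 10 fell, 1 rose and 13 did not pass (adjusted over the list alone, 12 fell and 1 rose). Besides Lhx2, the largest falls were of Gfap, an intermediate filament (-1.48, SE 0.07), Nes, the intermediate filament nestin (-1.31, SE 0.15), and Angptl6, a secreted angiopoietin-like factor (-0.92, SE 0.08). Reln, the secreted protein reelin, fell by 0.26 (SE 0.05). Lrat, the enzyme that esterifies retinol for storage, had a change of 0.10 (SE 0.07, adjusted p = 0.633) at a control level of 13.65, near the top of the value range, and Des, desmin, a change of 0.07 (SE 0.06, adjusted p = 0.688). The sort took cells by their retinoid autofluorescence. Cells that had lost their retinoids would be missing from both groups, which limits what Lrat, the retinoid genes and Acta2 can show. Adamtsl2 was the member that rose (0.65, SE 0.16), a call that was lost when any array except control 4 was left out (adjusted p up to 0.106). The list passed camera (adjusted p = 1.69e-06; adjusted p = 0.101 with an estimated correlation). Without control 1 and control 4, Reln had an adjusted p of 0.056 at a change of -0.29. Of 28 retinoid and lipid droplet genes, Lpl, lipoprotein lipase, rose (0.71, SE 0.09), and Aldh1a3, a retinoic acid synthesising enzyme (-0.96, SE 0.13), Plin2, a lipid droplet coat protein (-0.42, SE 0.05), and Rxra, a retinoid receptor (-0.26, SE 0.05), fell (adjusted over the list alone, 2 rose and 4 fell). This list passed fry (adjusted p = 0.00412) and did not pass camera (adjusted p = 0.194), although it did, as lower, without control 1 and control 4 (adjusted p = 0.028). The number risen went from 1 to 2 without control 3 or knockout 5, and Rxra lost its call without knockout 5, 6 or 7 (adjusted p up to 0.0612). The deleted gene Lhx2 counts in the tests of the identity list and of the list of mesenchymal and LIM transcription factors. Of 34 such factors, 8 fell, Lhx2 included, and 26 did not pass (adjusted over the list alone, 10 fell). Among the fallen were Id3 (-1.55, SE 0.13), Nr2f1, COUP-TFI (-0.57, SE 0.07), and Ldb2, a cofactor of LIM factors (-0.54, SE 0.05). Camera gave an adjusted p of 3.55e-06 for them (adjusted p = 0.124 with an estimated correlation), and the number fallen was 4 without control 1 and control 4.

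Growth factors of quiescent stellate cells changed in both directions. Of 20 measured, 5 rose, 6 fell and 9 did not pass (adjusted over the list alone, 6 rose and 6 fell). With Bmp10 and Gdf2, the fallen members included Rspo3, an enhancer of Wnt signalling, which went from 12.41 ± 0.03 to 11.34 ± 0.06 (SD, n = 4 each), and Hgf, hepatocyte growth factor, which fell by 0.37 (SE 0.06). Besides Gas6, the risen members were Igf1 (1.27, SE 0.23), Wnt4 (0.75, SE 0.17), Kitl, stem cell factor (0.65, SE 0.10), and the chemokine Cxcl12 (0.23, SE 0.05). The list did not pass camera (adjusted p = 0.628) but had the smallest directional fry p of the 32 lists (limma adjusted p = 1.05e-06), with a median of 0.02 and a mean of -0.05 that differed in sign. Leaving out control 2, knockout 7 or knockout 8 took the risen members from 5 to 3, since Wnt4 lost its call without each of them (adjusted p up to 0.0683). Cxcl12 lost its call without any array except control 3 and knockout 5 (adjusted p up to 0.0894), and without control 1 and control 4 Hgf had an adjusted p of 0.0601.

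Several signalling lists held changes in both directions without passing camera, of which the YAP targets passed fry. Of 28 Wnt pathway genes, 6 rose and 3 fell (adjusted over the list alone, 7 and 3; camera adjusted p = 0.172; median -0.02 and mean 0.20, of opposite sign). The risen members included Sfrp1, Dkk3, a secreted Dickkopf-family protein (1.39, SE 0.11), and the receptor Fzd2 (0.87, SE 0.11), and the fallen ones were Rspo3, Ccn4 (-0.81, SE 0.15) and Fzd1 (-0.31, SE 0.08). Of 19 hedgehog and Notch genes, 4 rose and 4 fell (adjusted over the list alone, 4 and 7; camera adjusted p = 0.496). Hey2, a Notch target, rose by 1.21 (SE 0.07), with the receptors Notch3 (0.57), Notch2 (0.39) and Smo (0.34), while Hhip, an inhibitor of hedgehog ligands (-1.61, SE 0.12), Hey1, another Notch target (-1.23, SE 0.10), Dll4, a Notch ligand of endothelium (-1.14, SE 0.20), and Notch1 (-0.30) fell. Leaving out control 2, control 4, knockout 5, knockout 6 or knockout 7 took the risen members of this list from 4 to 2: Notch3 was lost without each of them (adjusted p up to 0.0827) and Smo without every array in turn (up to 0.126). Notch1 was lost without control 4, knockout 5 or knockout 7 (up to 0.0647), and Fzd1 without any array except control 3 and knockout 7 (up to 0.112). Of 25 TGF-beta pathway genes and targets, 3 rose and 4 fell (adjusted over the list alone, 5 and 7; camera adjusted p = 0.552). The ligands Tgfb3 (0.73, SE 0.08) and Inhba (0.61) and the receptor Tgfbr1 (0.44) rose, and Id3, Id1, both targets of BMP signalling (Id1 -1.11, SE 0.19), Tgfb2 (-1.03, SE 0.15) and Pmepa1 (-0.26) fell. Tgfbr1 lost its call without control 3, knockout 5, 6 or 7 (up to 0.0785) and Pmepa1 without any array except control 4 and knockout 7 (up to 0.092). Of 16 YAP targets, F3, tissue factor (0.67), and Amotl2 (0.49) rose and Tead4 (-0.68) and Ajuba (-0.45) fell (adjusted over the list alone, 3 rose and 2 fell; camera adjusted p = 0.731, fry adjusted p = 0.00455). F3 lost its call without control 1, 2 or 4 or knockout 5 or 8 (up to 0.0958) and Amotl2 without control 4 or knockout 7 (up to 0.0603).

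Cholesterol synthesis genes rose together. Of 16 measured, 12 rose and 4 did not pass (adjusted over the list alone, 15 rose), with a list median of 0.60. Fdft1, squalene synthase, rose by 0.89 (SE 0.15), Sqle, squalene epoxidase, by 0.82 (SE 0.17), Insig1, a sterol-regulated brake on the pathway, by 0.75 (SE 0.19), and Cyp51, lanosterol demethylase, by 0.70 (SE 0.14). The list had the smallest camera p of the 32 (adjusted p = 1.83e-14; adjusted p = 0.124 with an estimated correlation). Leaving out control 2 or knockout 8 took the risen members from 12 to 7, and 4 passed without control 1 and control 4. Sqle lost its call without control 2 (adjusted p = 0.0504), Cyp51 without control 2 or knockout 8 (up to 0.0571), and Insig1 without any array except knockout 5 and knockout 6 (up to 0.118).

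Some interferon-stimulated genes were lower 2 weeks after the poly(I:C) that both groups received. Of 23 measured, 5 fell and 18 did not pass (adjusted over the list alone, 7 fell; camera adjusted p = 0.000245; adjusted p = 0.371 with an estimated correlation). The 5 were Ifit1 (-0.65, SE 0.15), Zbp1 (-0.51, SE 0.06), Ifit3 (-0.51, SE 0.07), Ifih1 (-0.30, SE 0.06) and Ifit2 (-0.27, SE 0.07), RNA or DNA sensors and effectors of the antiviral response. Leaving out knockout 5, 6 or 7 took them from 5 to 3, with Ifit1 at an adjusted p of up to 0.0805 and Ifit2, lost without any array except control 1, at up to 0.118. The list means of the groups overlapped, with control 1 at 10.16 and knockout 8 at 10.28 (exact two-sided permutation p = 0.0571). Control 1 was also the lowest control array, and knockout 8 the highest knockout array, in the endothelial score (7.84 and 9.78). Antigen presentation genes had 0 of 13 members past the threshold in limma, with 3 lower at an unadjusted p under 0.05 (adjusted over the list alone, 2 fell; camera adjusted p = 0.144). The largest differences were of Nlrc5 (-0.30, adjusted p = 0.0675), H2-Ab1 (0.24, adjusted p = 0.825), Psmb9 (-0.24, adjusted p = 0.168) and Cd74 (-0.19, adjusted p = 0.91). That list passed, as lower, without control 1 (adjusted p = 0.0419) or knockout 7 (adjusted p = 0.0274), and 1 member fell without control 3. Of 28 chemokines, cytokines and adhesion genes, Il33, an alarmin (0.94, SE 0.08), and Ccl19, a chemokine for lymphocytes (0.74, SE 0.11), rose and Ccl2, a chemokine for monocytes, fell (-0.55, SE 0.08), with Cxcl5 at 0.69 (adjusted p = 0.0822). Adjusted over the list alone, 4 rose and 3 fell; the list did not pass camera (adjusted p = 0.962), and its median of -0.05 and mean of 0.01 differed in sign. Without control 4, 2 of its members fell.

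Stress and cell cycle lists passed camera as lower but held few single calls and did not pass fry (adjusted p = 0.206 for the immediate-early and for the unfolded protein response list, 0.252 for the cell cycle list). An exact two-sided permutation test of their list means gave p = 0.143, 0.143 and 0.257, none past the threshold. Of 24 immediate-early and dissociation stress genes, Ier2 (-0.92, SE 0.23), Btg2 (-0.75, SE 0.18), Egr3 (-0.49, SE 0.09) and Klf6 (-0.34, SE 0.07) fell (adjusted over the list alone, 4 fell; camera adjusted p = 7.25e-05; adjusted p = 0.66 with an estimated correlation). Without control 1 and control 4, 0 members passed in limma, with 5 lower at an unadjusted p under 0.05. Leaving out control 2, control 4, knockout 5 or knockout 6 took the count from 4 to 2: Btg2 was lost without each of these (adjusted p up to 0.107) and Ier2 without any array except control 1 (up to 0.114). The immediate-early means were higher in control 2 and control 4 (12.06 and 12.10), the control arrays with the higher endothelial scores (10.59 and 11.06), than in control 1 and control 3 (11.68 and 11.62, at scores of 7.84 and 9.17). Of 20 unfolded protein response and secretory pathway genes, Dnajb9, an endoplasmic reticulum chaperone, fell (-0.41, SE 0.09; adjusted over the list alone, 1 fell; camera adjusted p = 0.00246; adjusted p = 0.66 with an estimated correlation). It lost its call without control 2, control 4 or knockout 8 (adjusted p up to 0.0585), and Ddit3, CHOP, had a change of -0.68 (adjusted p = 0.0927); without knockout 5, 3 members fell. Of 28 cell cycle genes, Mcm5, a replication helicase subunit, fell (-0.28, SE 0.06; adjusted over the list alone, 1 fell; camera adjusted p = 0.0072; adjusted p = 0.66 with an estimated correlation). Cdk1 had a change of 0.45 (adjusted p = 0.122) and Mki67 of -0.44 (adjusted p = 0.43). The camera call of the cell cycle list was lost without control 3 (adjusted p = 0.118) or knockout 8 (adjusted p = 0.0583), and that of Mcm5 without control 3, control 4 or knockout 6, 7 or 8 (up to 0.0733), while 2 members fell without control 2 or knockout 5.

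Transcripts of other liver cells were present, at levels that varied between arrays. Alb, albumin, had a log2 level of 13.04 ± 0.34 (SD, n = 4) in the knockout group, and a change of 0.04 (SE 0.31, adjusted p = 0.978). A hepatocyte score, the mean of 14 marker genes, was 9.76 ± 1.00 and 9.80 ± 0.66 (SD, n = 4 each; exact two-sided permutation p = 0.943), and an endothelial score of 12 genes was 9.66 ± 1.46 and 9.04 ± 0.70 (SD, n = 4 each; exact two-sided permutation p = 0.514). Of 18 hepatocyte markers 0 passed in limma and 1 was lower at an unadjusted p under 0.05 (adjusted over the list alone, 0; camera adjusted p = 0.884), the widest difference being Cyp2e1 at -1.21 (SE 0.43, adjusted p = 0.157); the list passed camera, as lower, without control 4 (adjusted p = 0.00909). Of 18 sinusoidal endothelial markers, Clec4g, a lectin, fell (-1.23, SE 0.25; adjusted over the list alone, 1 fell), and the list, with a median of -0.55, passed camera (adjusted p = 0.03; adjusted p = 0.775 with an estimated correlation) and did not pass fry (adjusted p = 0.462). That camera call was lost without control 2 (adjusted p = 0.261), control 4 (0.364) or knockout 5 (0.384), and that of Clec4g without control 2 or knockout 5 (up to 0.058); without control 1, 2 members fell.

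**Figure D3:**
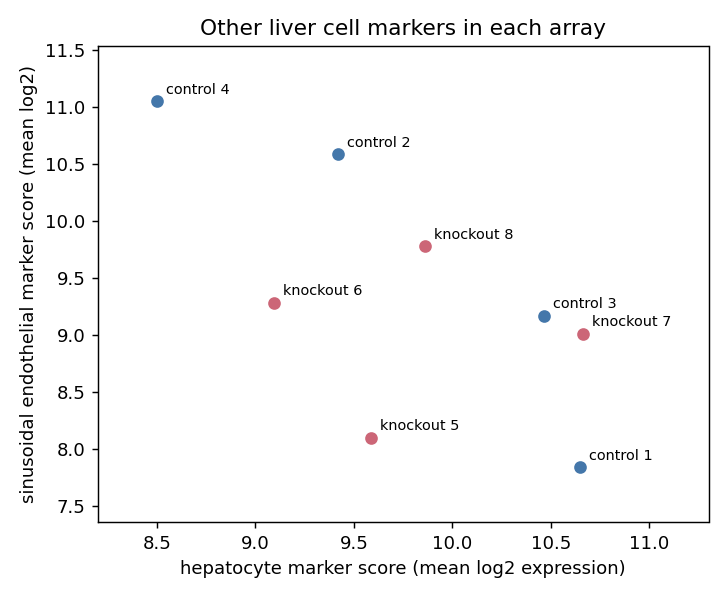
Mean log2 expression of 14 hepatocyte markers (x axis) and of 12 sinusoidal endothelial markers (y axis) in each of the 8 arrays. The control arrays spanned 8.50 to 10.65 on the hepatocyte score and 7.84 to 11.06 on the endothelial score, and the knockout arrays lay within the endothelial range of the controls. On the hepatocyte score knockout 7 (10.66) lay just above the highest control array.

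Portal fibroblast markers rose in part. Of 14 measured, Cd34, Dpep1, Dpt, Eln, elastin (0.81, SE 0.10), and Mfap4 (0.39, SE 0.05) rose and 9 did not pass (adjusted over the list alone, 7 rose; camera adjusted p = 1.26e-05; adjusted p = 0.101 with an estimated correlation). Dpt, Eln and Mfap4, and Fbln2, which passed only without control 1 (adjusted p = 0.0107) among the single arrays left out, are also members of the matrix list. Of 17 Kupffer cell and macrophage markers, Cd68, a lysosomal protein, fell (-0.61, SE 0.14; adjusted over the list alone, 2 fell; camera adjusted p = 0.172), with Vsig4 at -1.24 (SE 0.39, adjusted p = 0.104). Cd68 lost its call without control 1, 2 or 3 or knockout 6 or 7 (adjusted p up to 0.0852), and the list passed camera, as lower, without control 4 (adjusted p = 0.00772; 3 members fell) or knockout 7 (adjusted p = 0.0402). Mesothelial markers had 2 fallen of 13, Efemp1 and Wt1 (-0.24, SE 0.05), with 2 adjusted over the list alone and a camera adjusted p of 0.266; Wt1 lost its call without any array except knockout 5 and knockout 6 (up to 0.0879). Of 8 erythroid and platelet markers, Pf4, a platelet chemokine, rose (0.69, SE 0.09) and Itga2b, a platelet integrin, fell (-1.44, SE 0.07), as they did adjusted over the list alone (camera adjusted p = 0.731, fry adjusted p = 0.0139). Monocyte and dendritic cell markers (11 measured), B cell markers (9), T and NK cell markers (15), neutrophil markers (12) and cholangiocyte markers (12) each had 0 members past the threshold in limma, over all genes, adjusted over the list alone and at an unadjusted p under 0.05. Their camera adjusted p were 0.731, 0.994, 0.548, 0.884 and 0.731. The control list means of the B cell (6.24), T and NK cell (6.26), neutrophil (6.31) and cholangiocyte markers (6.62) lay under 6.77, the guide to unexpressed levels. A change of most of these genes may therefore not be measurable. The pan-leukocyte gene Ptprc had a change of 0.28 (SE 0.17, adjusted p = 0.508) at a control level of 6.84, close to the 95th percentile of 6.77 of 1194 olfactory and vomeronasal receptor genes. The 4 sex-linked genes measured did not pass, 1 being higher at an unadjusted p under 0.05 (adjusted over the list alone, 0; camera adjusted p = 0.479), with Xist at 5.56 in the control and 5.63 in the knockout group and the Y-linked Uty at 9.34 and 9.28.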

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

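No explanation was tested for the values in this part. A single array stood apart from the other 3 of its group in 24 of 476 groups of 4 arrays, where chance gives about 1 in 20, or 23.8. What set them apart was the gap to the nearest array as a share of the group's range, which exceeded Dixon's critical value for 4 samples and is given for each. Among knockout arrays, knockout 7 stood apart for C7 (0.907), Raet1d (0.847), Cxcl5 (0.968), Cldn7 (0.883), Mfap4 (0.836) and Id4 (0.831), knockout 8 for Htra1 (0.940), Me1 (0.857) and the mean of the collagens (0.863), knockout 5 for Tead4 (0.834) and the means of the cholangiocyte (0.862) and the erythroid and platelet markers (0.862), and knockout 6 for Gpm6a (0.931). Among control arrays, control 4 stood apart for Cd68 (0.842), Zbtb46 (0.834), Wnt4 (0.943) and Sema3f (0.941), control 1 for Pi15 (0.841) and Nr1h4 (0.874), control 2 for Gfap (0.831), Fdft1 (0.885) and the mean of the collagens (0.899), and control 3 for Egr3 (0.852) and Pf4 (0.905). Even so, control and knockout arrays overlapped only for Zbtb46 and Cldn7 among these genes.

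Among the 12146 probe sets with no listed gene, which entered no comparison above, 42 passed the threshold when tested on their own in limma, 22 higher and 20 lower in the knockout.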

How the results depend on the processing

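The alternatives with marker scores as covariates and without control 1 and control 4 were chosen after the data were seen. No paired analysis was possible because the groups share no replicate number. The count of 1472 changed genes stayed within 1.5 times under every change of normalization, filter, variance model, weighting, probe set rule and single left-out array, from 1010 without knockout 6 to 1892 with array weights. With the marker scores as covariates 1617 genes changed, 1304 of them shared. It moved to 523 with the 1.5-fold threshold, to 775 at an adjusted p under 0.01, which follow from the stricter thresholds, and to 776 (371 higher, 405 lower) without control 1 and control 4, a fit with fewer arrays. Lhx2 stayed lower and past the threshold throughout, from -0.73 to -0.59 with 1 array left out. The 30 largest changes passed in every alternative that gave them a test, and Acvr1c was not tested with the filter at the median. The number of lists past the threshold was 14, and lay between 13 and 16 with 1 array left out. It was 12 with the marker scores, 17 without control 1 and control 4, 15 with array weights, and 0 with an estimated correlation, a test that allows for the measured correlation of the genes in a list. Of 146 named genes past the threshold besides Lhx2, 104 kept the call in every setting that tested them, 42 lost it in at least 1 setting, 36 of them without control 1 and control 4, and 0 turned sign. Of 59 named genes not past the threshold, 15 passed in at least 1 setting and 16 turned sign in at least 1. The signs turned, with the cause not tested, for Elane with array weights (0.0018) and Pi16 with quantile normalization (0.0063); with the marker scores for Cd74 (0.23), Uty (0.0074), Eif2s3y (0.043), Cd79a (0.018), Mpo (-0.0038) and Tff2 (-0.0093); and without control 1 and control 4 for H2-Ab1 (-0.096), Zbtb46 (0.0042), Ppbp (-0.031), Pi16 (0.028) and Alb (-0.19). With 1 array left out the log2 change ran from -0.53 to 0.14 for Cd74, -0.13 to 0.024 for Plac8, -0.0015 to 0.17 for Cav1, -0.091 to 0.053 for Eif2s3y, -0.083 to 0.82 for Cps1, -0.082 to 0.0096 for Zbtb46, -0.29 to 0.22 for Alb, -0.14 to 0.0037 for Uty, -0.14 to 0.017 for Cd79a, -0.020 to 0.28 for Ppbp, -0.040 to 0.041 for Pi16 and -0.14 to 0.022 for S100a9. Genes with levels near those of the receptor genes (median 5.40) have little signal over background, so small changes there are not measurable.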

Other observations

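The gene families and the fatty acid list were chosen after the values were seen, as were the tests of carry-over and of portal fibroblasts below. Among 31 activin and BMP ligands and receptors, 5 rose and 6 fell in limma: Bmp4 rose by 0.69 (SE 0.08) and Bmp6 by 1.22 (SE 0.29), while Bmp5 fell by 0.36 on the log2 scale (SE 0.05) with Bmp10 and Gdf2, and the receptor Acvr2a fell by 0.71 on the log2 scale (SE 0.05). Bmp6 lost its call without control 3 or any knockout array (adjusted p up to 0.0888). Of 42 nuclear receptors, 1 rose and 6 fell, with Nr1h4, the bile acid receptor FXR, falling from 12.32 ± 0.06 to 10.77 ± 0.09 (SD, n = 4 each) along with its relative Nr1h5. The riser was Esr2, from a control level of 6.77, the 95th percentile of the olfactory and vomeronasal receptor genes, to 7.50, a call lost without control 2, control 3 or knockout 6 (adjusted p up to 0.0651). Of 32 complement components, complement receptors and C1q-like genes, 4 rose and 2 fell; C4b rose by 0.46 (SE 0.08) beside C7, while C6, of the same terminal complex as C7, fell by 1.74 (SE 0.09). All 3 HtrA proteases that passed, of 4 measured, rose, with Htra3 at 1.82 (SE 0.09).

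Of 29 semaphorins and plexins, 3 rose and 8 fell, among them Plxna4 (2.10, SE 0.13), Sema4d (-0.76, SE 0.09) and Sema3f (-0.69, SE 0.07). Integrin subunits had 5 risen and 3 fallen of 31, including Itga3 (1.06, SE 0.13), Itga8 (0.81, SE 0.07) and Itgb3 (-0.74, SE 0.12), and Eph receptors and ephrins 3 and 2 of 21, including Epha4 (1.40, SE 0.12). The glutamate receptor subunit Grin2b fell by 1.65 (SE 0.08). ADAMTS and ADAMTS-like genes had 6 risen and 3 fallen of 23, FGF ligands and receptors 2 and 2 of 26, and 0 of 7 Igfbp genes passed in limma, with 2 at an unadjusted p under 0.05. Of 11 fatty acid synthesis genes, 4 rose and 1 fell: Elovl6 (1.19, SE 0.16), Scd2 (0.85, SE 0.08), Acss2 (0.48, SE 0.07) and Fasn (0.46, SE 0.10) rose and Me1 fell (-0.50, SE 0.07), with a median of 0.19. Fasn lost its call without control 2, control 4 or knockout 7 (adjusted p up to 0.0664).

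The counts of changed genes were compared over all ways to split the 8 arrays into 4 and 4. Of the 35 splits, 1, the real one, gave 1472 changed genes, 749 higher and 723 lower. The highest count of any other split was 0. With 1 of 35 as the smallest share this test can give, a chance assignment to the groups is unlikely but not excluded. Every other split mixes control and knockout arrays, which widens the spread within its groups. A count of 0 there does not measure the strength of the result. The test also does not tell whether the arrays stand for separate animals.

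With the hepatocyte and endothelial scores as covariates, the median rise of the 23 risen matrix and collagen genes was 0.87 (bootstrap interval 0.56 to 1.40), against 0.82 without them. The scores thus did not take away the rise of these genes. The 23 were picked by their rise in the same arrays, so the value does not decide on carry-over of those cells. Over all 47 members of both lists, chosen without regard to their values, the median was 0.23 (interval 0.086 to 0.56) with the scores and 0.23 without, an interval too wide to decide for the lists as a whole, although both passed camera with the scores (adjusted p = 1.17e-12 and 4.76e-05). Portal fibroblasts, which a retinoid-based sort should remove, would also bring matrix transcripts, and may account for part of the rise: the 10 portal fibroblast markers outside the matrix list had a median of 0.093 (interval -0.054 to 1.26), since Cd34 and Dpep1 rose while 8, such as Thy1 (-0.10, at a control level of 7.51) and Pi16 (-0.01, at 6.81, with a sign that turned under quantile normalization), did not pass; Cd34 reached 10.97 in the knockout. Not all of the 8 were dim: Gas1 (0.25, at a control level of 10.97), Cd248 (0.13, at 10.68) and Entpd2 (-0.29, at 8.81) did not pass either. Of the 10 markers 2 rose, 0 fell and 8 did not pass, and the interval of their median runs from under 0 to above 0.82. Portal fibroblasts and a change within stellate cells therefore cannot be told apart here.

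The fall of Id1 and Id3, both targets of BMP signalling, came with the falls of Bmp10 and Gdf2. With both scores as covariates the mean of Id1 and Id3 was -1.29 (2 standard errors reach from -1.58 to -0.99), against -1.33 without. The scores thus did not take away the fall of these genes. Id1 and Id3 were picked by their fall in the same arrays, so the value does not decide on endothelial RNA. Lower BMP9 and BMP10 signalling in the stellate cells themselves is a hypothesis that stays open. The 6 other BMP targets had a median of -0.022 (interval -0.57 to 0.027), with members on both sides of 0. The members nearest 0, Msx2, Smad9, Msx1 and Nog, had control levels of 6.68, 7.44, 8.01 and 7.23. Id4 (8.47) and Atoh8 (9.75) had higher control levels. The median thus rests on the dimmer genes and does not decide. Id4 fell (-0.76, SE 0.19), a call lost without any array except control 1 and control 3 (adjusted p up to 0.126), and Atoh8 was at -0.38 (adjusted p = 0.16). Id2 (-0.61, limma adjusted p = 0.103) and Smad6 (-0.36, limma adjusted p = 0.0634) were not among the 6 and did not pass. Smad7 (-0.09, limma adjusted p = 0.80) and Bambi (-0.10, limma adjusted p = 0.63) did not pass either and lay nearer 0. These genes belong to the TGF-beta list, where 3 genes rose and 4 fell.

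The rise of cholesterol synthesis genes had a median of 0.63 (interval 0.51 to 0.73) with both scores as covariates and 0.60 without. The scores did not take away the rise, which argues against hepatocyte or endothelial carry-over as its whole cause. That interval covers the choice of genes, not the spread between arrays, and carry-over of other cells was not tested. A lower sterol content of the knockout cells may lie behind the rise, in which case targets of the sterol sensor LXR should fall. Their median over 8 genes was 0.0030 (interval -0.12 to 0.40), with Srebf1 (0.98, SE 0.09) and Lpcat3 (0.40, SE 0.07) higher, so the test does not decide. Srebf2, the regulator of the pathway, rose by 0.67 (SE 0.08).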
